A study of Danio rerio with 12 samples.

How the data were processed

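RNA was measured in 12 libraries of pooled whole zebrafish larvae, 3 each from solvent control, 3, 30 and 100 nM tributyltin chloride (TBT), with 10 larvae per pool. Per the labels' protocols, 500 ng of RNA went into a stranded poly(A) library kit with 15 PCR cycles, and paired reads of 76 nt were sequenced at an average of 42000000 pairs per library. The submitters' processing notes name CASAVA, STAR 2.5.1b, RSEM 1.2.28 and DESeq2 1.10.1 and the genome build GRCz10, with no role or order, and the annotation release is not given in the sources used here. The deposited values are a score, not raw counts: per the file headers they are normalised counts, whole numbers after division by a size factor per library. The deposited series table held the same values for 12 of the 12 libraries and was not used a further time. No genome of that build was used here, so genes carry no coordinates.

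Each library listed 26816 genes, 24420 of them protein-coding, and 578 gene names were shared by more than 1 gene ID. Of the gene IDs, 24005 matched the gene name table used here. Each library's size factor was estimated from the steps between its low values, with 19 of 20 simulated libraries resolved, all 19 within 1% of the true factor. The factors lay between 0.812 and 1.629 for 11 libraries, which gave raw totals of 23800000 to 49700000, and 100 nM replicate 2 was not resolved. The most abundant gene, zgc:158463, took 2.05% to 4.57% of the values. Libraries of the same group correlated across genes at r between 0.948 and 0.989 and shared 193 to 436 equal values, so that none was treated as a duplicate. Genes in families of near-identical copies, such as opsins, globins, cyp2 genes, sulfotransferases, C-reactive proteins and elastases, may share reads and are uncertain.

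Groups, comparisons, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The plan was a count test with edgeR, which these values do not allow, so log2(value + 1) was tested with limma 3.58.1 in R 4.3.3 (linear model on all 12 libraries, moderated by eBayes with a variance trend). The pseudocount was 1. Genes with a value of at least 10 in at least 3 libraries were tested, 22404 in all, of which 18742 had a symbol. P-values were adjusted by the Benjamini-Hochberg method over these genes, with a threshold of 0.05. Replicate numbers in the labels were not used as a block.

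The 37 gene lists, of pathways and of cell type and tissue markers, held 1416 symbols, of which 1333 matched a gene. Lists with at least 5 tested members were tested by limma's camera with a preset correlation of 0.01 and adjusted over the lists; camera with an estimated correlation and fry were alternatives. A count adjusted over the list alone used the p-values of the list's own members. Lists used only in the closing observations were written after the data had been seen and adjusted among themselves.

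Genes were named by rule. For 100 and 30 nM these were the 8 largest rises and 8 largest falls past the threshold, with a symbol, a mean of at least 5 CPM (per total of the values) and all treated libraries outside the control range; the 3 members with the lowest p from every list with 3 or more members past the threshold; and, whatever their result, the RXR genes, pparg, cyp19a1a, cyp19a1b and cyp26a1. For 3 nM they were the genes past the threshold, at most 5 each way by lowest p, and the genes named at 100 nM. For 100 against 30 nM they were the 5 largest rises and falls. Genes named outside the rule are marked as chosen after their values were seen.

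For each gene past the joint test of the 4 groups, log2(value + 1) was fitted against concentration with a linear, a power (exponent 1 to 4) and a Hill curve, and the curve with the lowest AICc was kept (2003 linear, 508 power, 370 Hill). The benchmark dose was the concentration at which that curve had moved by 1 residual SD. Doses above 100 nM (39 genes) or below 0.3 nM (88 genes) were left out, and lists with 3 or more genes were given a median.

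The methods were tested on simulated data with known answers. With about 200 genes changed by known folds, limma recovered 16.4% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 81.8% of those changed 4-fold at 100 nM (22345 genes, 6 false among 109 calls); 16.4%, 47.8% and 78.8% at 30 nM (22352 genes, 6 false of 101); and 26.9%, 47.8% and 75.8% at 3 nM (22353 genes, 2 false of 102). Between 100 and 30 nM it recovered 16.4%, 38.8% and 75.8% (22351 genes, 5 false of 92). The real data gave 3926 calls at 100 nM and 2069 between 100 and 30 nM. With so many calls the Benjamini-Hochberg method admits larger unadjusted p-values, so these shares do not give the sensitivity of those 2 comparisons. Of the 37 lists, 0 were called without an effect and 1 with 1 list moved. The simulated genes were drawn independently of each other and without a replicate effect. These counts therefore do not show how often camera calls lists falsely in the real data. Other splits of the real libraries, given at the end, called up to 23 lists. For 1000 simulated genes with a benchmark dose of 20 nM the median estimate was 19.5 nM, and 15.3 nM by interpolation.

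Alternatives were upper-quartile scaling, no filter on low values, a filter of 1 CPM in 6 libraries, a replicate block, a pseudocount of 0.5, only the 2 groups compared, an added 1.5-fold minimum, and each library left out in turn; for lists also ranks, and for benchmark doses a response of 2 SD, linear curves only, interpolation and 1.5-fold genes. Scaling every library to the same total of values, called equal totals in the text, a robust prior and no variance trend were added after the data were seen, as was upper-quartile scaling for list counts, benchmark doses and the overlap.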

Results

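The data comprised RNA-seq of whole wild-type zebrafish eleutheroembryos, the larval stage after hatching and before independent feeding, collected at 5 days post fertilization (dpf). The larvae had been kept from 2 to 5 dpf in water with tributyltin chloride (TBT) at 3, 30 or 100 nM, or with the solvent alone (0.2% v/v dimethyl sulfoxide, the control). TBT is an organotin biocide known to bind the retinoid X receptors (RXR) and PPARγ. Each of the 4 groups held 3 libraries, and each library came from a pool of 10 larvae. Nothing in the sources used here says that the pools of a group came from separate clutches or exposures, so every p-value measures the spread between these pools, which may be technical.

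The values were normalised counts for 26816 genes, of which 22404 were tested. Their sum per library was 28300000 ± 1970000 in the control, 30200000 ± 1720000 at 3 nM, 29600000 ± 1540000 at 30 nM and 32300000 ± 3150000 at 100 nM (SD, n = 3 each). The raw totals, estimated from the steps between low values, lay between 23800000 and 49700000 for 11 of the 12 libraries, and that of 100 nM replicate 2 could not be resolved. The first 2 principal components held 29.3% and 28.8% of the variance, and the 100 nM libraries had the scores 39.9, 72.0 and 46.1 on the second. On the first component, control replicate 2 lay at 71.7 and 100 nM replicate 1 at −56.6, so that this component did not follow the groups. In each group replicate 1 lay lowest on it and replicate 2 highest, so that it ran with the replicate numbers. All fold changes were computed on log2(normalised count + 1), which understates the change of genes with low values.

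**Figure D1:**
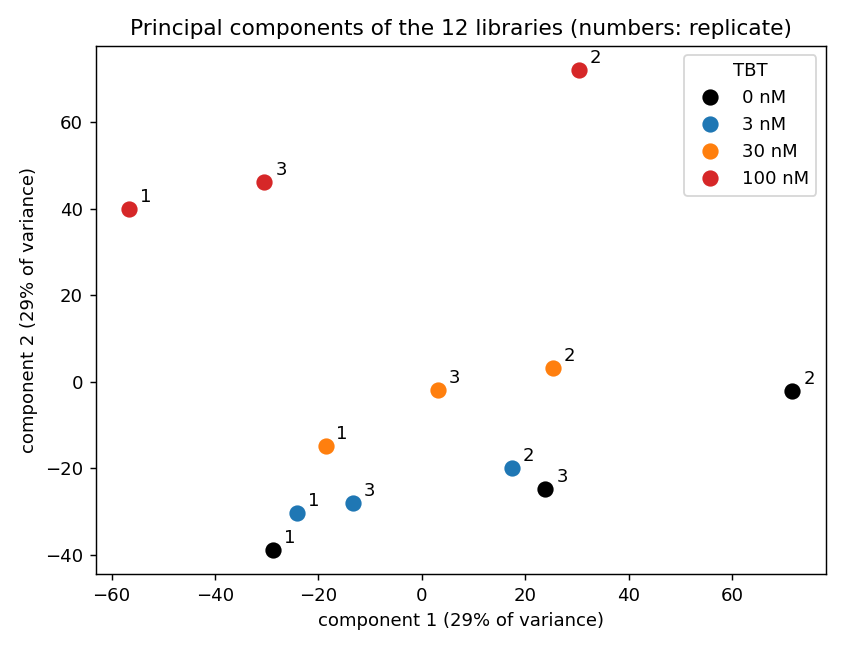
Principal components of log2(normalised count + 1) over the tested genes: component 1 (29.3% of the variance) on the x axis, component 2 (28.8%) on the y axis, 1 point per library, coloured by TBT concentration and marked with its replicate number. The 100 nM libraries lie at 39.9, 72.0 and 46.1 on component 2, while component 1 runs from 100 nM replicate 1 at −56.6 to control replicate 2 at 71.7.

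The comparison of 100 nM TBT with the control asked which transcripts changed at the highest concentration. opn1lw1 (ENSDARG00000044862), a red cone opsin gene, rose 18-fold, from 83 ± 24.8 normalised counts in the control to 1506 ± 399 at 100 nM (SD, n = 3 each, log2 fold change 4.17 ± 0.24 SE, limma adjusted p = 4.75e-06). lyve1a (ENSDARG00000075833), a hyaluronan receptor gene of lymphatic endothelium, rose 10.8-fold, from 59 ± 11 to 640 ± 3.51 (adjusted p = 1.34e-06). soat2, which encodes a sterol O-acyltransferase, rose 9.43-fold, from 106 ± 5.03 to 1072 ± 428 (adjusted p = 3.85e-05). Among the largest falls, slc15a1a (ENSDARG00000100315), a peptide transporter gene, went from 569 ± 295 to 37.7 ± 25.4 (log2 fold change −3.98 ± 0.43 SE, adjusted p = 1.81e-04), and enpp7.1, which encodes an alkaline sphingomyelinase of the gut, from 780 ± 271 to 65.7 ± 4.16 (−3.50 ± 0.27 SE, adjusted p = 2.29e-05). fosab, a subunit gene of the AP-1 transcription factor, went from 6044 ± 2594 to 593 ± 99.5 (−3.27 ± 0.43 SE, adjusted p = 5.31e-04). The other large rises were hbz (5.52), cyp2k18 (4.02), ppp1r27b (3.78), cyp2x12 (3.68) and sult3st4 (3.06), and the other large falls mslna (−4.26), URGCP (−3.73), rhcgl1 (−3.58), fut9d (−3.55) and SYCN (−3.07), all as log2 fold changes with an adjusted p of 0.00172 or lower. The opsins, globins, cyp2k and cyp2x genes and sulfotransferases have near-identical relatives, so their individual values are uncertain.

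In all, 3926 of the 22404 genes tested passed the threshold at 100 nM, 2157 higher and 1769 lower, with 612 and 537 of them changed more than 2-fold and a median absolute log2 fold change of 0.73 (limma). The count fell to 2289 without control replicate 3 and to 1172 with only the 2 groups in the fit, and 2587 genes also had a 1.5-fold change. With the replicate number as a block the count was 7678 (3790 higher, 3888 lower). Scaling all libraries to the same total of values, an alternative chosen after the data were seen, moved the median log2 fold change of all genes from −0.02 to −0.20 and the split from 54.9% higher to 28.2% higher (1127 higher, 2865 lower). Of the 37 gene lists, 20 were called by camera with its preset correlation, 13 of these also by fry, and 0 with an estimated correlation, where the lowest adjusted p was 0.131. That p accompanies each called list below. Among the single genes below that were named after their values were seen, me3 and ppox lost their calls without 11 of the 12 libraries taken in turn (adjusted p up to 0.106 and 0.14), amy2al1 without 10 (0.157) and slc2a2 without 6 (0.122). cyp17a1, tgfb1a, pax6b, syn1, gad2 and slc6a1b lost theirs without 4 (up to 0.112), ccl25b and tdo2a without 3 (up to 0.0914), and hsp90b1, hamp and dusp1 without 1 (up to 0.0642). With equal totals hmgcrb (0.117), acsl1b (0.0604), acadvl (0.207), tgfb1a (0.0678) and amy2al1 (0.0956) lost theirs.

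Receptors and lipid genes moved in both directions at 100 nM. rxraa, one of the RXR genes, fell from 743 ± 21.5 to 572 ± 34.2 normalised counts (SD, n = 3, log2 fold change −0.38 ± 0.08 SE, adjusted p = 0.00781). rxrgb passed the threshold (0.40, adjusted p = 0.0392) but lost it without 8 of the 12 libraries taken in turn, with adjusted p between 0.0212 and 0.135, and with equal totals (0.169). rxrbb (0.34, adjusted p = 0.0508), rxrab (−0.28, 0.508), rxrba (0.12, 0.336), rxrga (−0.21, 0.634), pparg (0.35, 0.114), cyp26a1 (0.10, 0.665) and cyp19a1b (0.37, 0.6) were not called, and cyp19a1a, with values from 0 to 5, was not tested. Of 19 tested genes of RXRs, PPARs and their partners, 4 rose and 1 fell (5 and 1 adjusted over the list alone), among the rises thraa (0.97, adjusted p = 4.68e-04), a thyroid hormone receptor gene, and nr1h3 (0.51, adjusted p = 0.00537), the LXR gene, which lost its call with equal totals (0.155). The list was called higher (median 0.16, camera adjusted p = 0.0419, adjusted p = 0.266 with an estimated correlation). That call ended without control replicate 2 (0.0669), control replicate 3 (0.0528) or 100 nM replicate 2 (0.106), and with equal totals (0.159, median −0.03) or a stricter filter on low values (0.056). Equal totals left 1 higher and 1 lower.

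Of 27 tested genes of LXR targets and fatty acid synthesis, 10 rose and 1, me3 (−0.32, named after its value was seen), fell at 100 nM (12 and 2 adjusted over the list alone). scd, which encodes a fatty acid desaturase, went from 18.3 ± 0.577 to 307 ± 50.7 normalised counts (SD, n = 3, log2 fold change 3.98 ± 0.21 SE, adjusted p = 4.13e-06). abca1a, which encodes a cholesterol efflux transporter, went from 4541 ± 591 to 15182 ± 1740 (1.74 ± 0.12 SE, adjusted p = 1.22e-05), and pltp, which encodes a phospholipid transfer protein, rose 4.88-fold (adjusted p = 1.15e-04). The list was called higher (mean 0.50, median 0.07, camera adjusted p = 0.00284, adjusted p = 0.326 with an estimated correlation), but not by camera on ranks (0.0677), and with equal totals its median was −0.11, with 8 members higher and 3 lower. In cholesterol biosynthesis, 9 of 27 genes fell and 1, hmgcrb (0.48, named after its value was seen), rose (12 and 1 adjusted over the list alone). Their median was −0.51 (camera adjusted p = 4.88e-04, adjusted p = 0.436 with an estimated correlation). Squalene epoxidase gene sqlea went from 176 ± 48.9 to 46.3 ± 11.7 (−1.90 ± 0.28 SE), and cyp51 (−1.21) and fdft1 (−0.71) fell with it.

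Of 32 lipid droplet and adipocyte genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone). The median was 0.25 (camera adjusted p = 0.0206, adjusted p = 0.266 with an estimated correlation). The leptin gene lepb rose from 1 ± 1 to 75.3 ± 12.6 normalised counts (adjusted p = 7.14e-05) and the perilipin gene PLIN5 2.11-fold. The call ended without control replicate 3 (0.0528), 100 nM replicate 1 (0.0521), replicate 2 (0.0919) or replicate 3 (0.065), and with the stricter filter (0.0826). With equal totals 4 rose and 4 fell. Lipoprotein and lipid absorption genes went both ways, 8 of 36 higher and 6 lower (10 and 7 adjusted over the list alone), with soat2 and lcat (1.72) among the rises and scarb1 (−1.81), an HDL receptor gene, among the falls. Their median was 0.02, their mean −0.08 and the camera direction up (adjusted p = 0.765), and the median was −0.17 with equal totals, with 3 higher and 7 lower. Among 32 fatty acid oxidation genes, 6 fell and 2 rose (7 and 2 adjusted over the list alone). Their median was −0.11 (camera adjusted p = 0.154). The falls included acsl1a (−0.66), eci1 (−0.60) and acads (−0.55), and the rises, named after their values were seen, were acsl1b (0.69) and acadvl (0.44). Equal totals gave 10 falls and 0 rises.

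Among 30 retinoid and vitamin D genes, 4 rose and 4 fell (4 and 4 adjusted over the list alone, median 0.04, mean −0.04, camera direction up, adjusted p = 0.91), and the median was −0.15 with equal totals, with 1 higher and 5 lower. cyp24a1, which encodes the vitamin D 24-hydroxylase, rose from 1397 ± 348 to 7398 ± 3479 normalised counts (SD, n = 3, log2 fold change 2.34 ± 0.35 SE, adjusted p = 0.00108), while cyp27b1, the gene of the enzyme that activates vitamin D, fell from 34 ± 10 to 7 ± 2.65 (−2.14 ± 0.32 SE, adjusted p = 0.0011), and bco1, the gene of a carotene oxygenase, fell 2.81-fold. Of 25 bile acid genes, 8 rose and 1 fell (9 and 5 adjusted over the list alone). The median was 0.20 (camera adjusted p = 0.158). Called genes included nr0b2b (4.33 ± 1.53 to 67 ± 39.1), fabp6 (1.4) and slc51a (1.28). Equal totals left 3 higher and 3 lower, with a median of 0.01. Of 22 steroid hormone synthesis genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone). Their median was 0.39 (camera adjusted p = 0.154). Called genes included hsd17b2 (0.89) and, named after its value was seen, cyp17a1 (−1.06), and equal totals gave 1 higher and 2 lower. Of 19 thyroid axis genes, 5 rose and 1 fell (6 and 2 adjusted over the list alone). The median was 0.10 (camera adjusted p = 0.158). Called genes included the deiodinase genes dio3b (1.17) and dio1 (−0.92), and the median was −0.09 with equal totals, with 3 higher and 1 lower. Of 9 vitellogenin and oestrogen responsive genes, 2 rose, vtg7 (3.06) and tgfb1a (0.56), both named after their values were seen (2 and 0 adjusted over the list alone). Their median was 0.04, or −0.15 with equal totals (camera adjusted p = 0.545).

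Of 42 genes of the aryl hydrocarbon receptor and drug metabolism, 8 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.158). cyp1b1 rose 4.49-fold, from 100 ± 5.51 to 462 ± 101 normalised counts (SD, n = 3, adjusted p = 4.2e-05), and sult1st2 fell by 2.24 on the log2 scale; the list's median was 0.03, or −0.15 with equal totals. In the list of oxidative stress and metal response, 18 of 36 genes rose and 2 fell (19 and 4 adjusted over the list alone). The median was 0.49 (camera adjusted p = 2.86e-05, adjusted p = 0.266 with an estimated correlation). Its rises included slc7a11, the gene of the cystine transporter (2.04 ± 0.25 SE), gclm, of glutathione synthesis (1.35 ± 0.15 SE), and the ferritin gene fth1a, from 23316 ± 786 to 46312 ± 5109. Heat shock and unfolded protein response genes numbered 16 higher and 6 lower of 39 (18 and 6 adjusted over the list alone, median 0.32, camera adjusted p = 9.79e-04, adjusted p = 0.266 with an estimated correlation), led by sesn2 (1.64), trib3 (1.49) and ddit3 (1.23), which are known for the response to amino acid and endoplasmic reticulum stress. Among the falls, all named after their values were seen, were the endoplasmic reticulum chaperone genes calr (−0.88), pdia4 (−0.68) and hsp90b1 (−0.62). Of 33 genes of the p53 response and apoptosis, 8 rose and 2 fell (9 and 2 adjusted over the list alone). Called genes included phlda3 (1.32), casp9 (1.08) and btg2 (−2.0). The list was called higher (median 0.30, camera adjusted p = 0.0143, adjusted p = 0.562 with an estimated correlation) but not by fry (0.0567), nor without control replicate 2 (0.137) or 100 nM replicate 1 (0.0599). With equal totals 6 rose and 4 fell.

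Inflammation and acute phase genes rose at 100 nM in 19 of 39 cases and fell in 3 (21 and 3 adjusted over the list alone). Their median was 0.64 (camera adjusted p = 1.18e-05, adjusted p = 0.131 with an estimated correlation). socs3b, a feedback inhibitor gene of cytokine signalling, went from 646 ± 54.2 to 1537 ± 125 normalised counts (SD, n = 3, log2 fold change 1.25 ± 0.10 SE, adjusted p = 3.69e-05), the chemokine gene cxcl18b rose 4.32-fold and the C-reactive protein gene crp3, which has near-identical copies, 3.11-fold. The falls were fosab (−3.27) and, named after their values were seen, junbb (−1.61) and hamp (−1.52). Equal totals left 12 higher and 3 lower. Of 47 complement and coagulation genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.47, camera adjusted p = 4.4e-04, adjusted p = 0.562 with an estimated correlation, fry adjusted p = 0.124), with C4A (2.76), C2 (2.44) and c7a (1.3) among them, and 5 of 47 rose with equal totals. Antiviral genes were split, 3 of 20 higher and 2 lower (4 and 2 adjusted over the list alone, median −0.02, mean −0.08, camera direction up, adjusted p = 0.572), from isg15 (27 ± 7.94 to 188 ± 22.7) to ifit14 (30.3 ± 15.4 to 0.667 ± 0.577).

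Among marker lists of blood and immune cells, 7 of 18 lymphocyte and thymus genes fell and 1, ccl25b (0.70, named after its value was seen), rose (9 and 1 adjusted over the list alone). The median was −0.51 (camera adjusted p = 0.0047, adjusted p = 0.306 with an estimated correlation). Called genes included ccr9a (−1.29), rag2 (−0.92) and runx3 (−0.51). Neutrophil markers counted 6 higher and 1 lower of 17 (7 and 2 adjusted over the list alone, median 0.11, or −0.07 with equal totals, camera adjusted p = 0.161), with mmp9 (1.90) and srgn (0.94) among the rises, and 3 higher and 2 lower with equal totals. Macrophage markers counted 3 higher and 2 lower of 23 (3 and 4 adjusted over the list alone, median 0.28, camera adjusted p = 0.351), with marco (1.82) higher and lgals3bpb (−2.30) lower, and 3 higher and 5 lower with equal totals (median 0.10). Of 27 erythrocyte and haem genes, 9 rose and 1, ppox (−0.65, named after its value was seen), fell (12 and 1 adjusted over the list alone). Their median was 0.58 (camera adjusted p = 8.44e-05, adjusted p = 0.377 with an estimated correlation). They included the embryonic globin genes hbz, from 22 ± 8 to 1019 ± 202 normalised counts (SD, n = 3), and hbbe2, from 2341 ± 774 to 9549 ± 2460.

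The lists of the digestive organs had medians from −1.45 to 0.40 at 100 nM. Of 29 genes of the exocrine pancreas and digestive enzymes, 13 fell and 1, amy2al1 (0.68, named after its value was seen), rose (18 and 1 adjusted over the list alone). The median was −1.45 (camera adjusted p = 9.26e-08, adjusted p = 0.436 with an estimated correlation). pla2g1b, a pancreatic phospholipase gene, went from 1105 ± 211 to 242 ± 167 normalised counts (SD, n = 3, log2 fold change −2.38 ± 0.39 SE, adjusted p = 0.00193), with CELA1 (−2.33) and sycn.2 (−2.0) lower as well. Of 38 enterocyte and gut markers, 7 fell and 2 rose (13 and 2 adjusted over the list alone, median −0.77, camera adjusted p = 4.4e-04, adjusted p = 0.562 with an estimated correlation, fry adjusted p = 0.134), with slc15a1a and mep1a.1 (−1.82) among the falls, and DAB2 (1.15) and, named after its value was seen, fabp6 (1.4) as the rises. Of 34 hepatocyte markers, 5 rose and 2 fell (8 and 3 adjusted over the list alone). Their median was 0.40 (camera adjusted p = 0.0485, adjusted p = 0.653 with an estimated correlation, fry adjusted p = 0.291). fabp10a, the liver fatty acid binding protein gene, rose 2.52-fold and ambp 1.95-fold, while ahsg2 fell from 98 ± 22.5 to 6 ± 2. The hepatocyte call ended without control replicate 1 (0.144) or 3 (0.0528), 3 nM replicate 1 (0.055), 2 (0.052) or 3 (0.0522), 30 nM replicate 2 (0.0627), or 100 nM replicate 2 (0.202) or 3 (0.238), and with the stricter filter (0.0623). Equal totals gave 3 hepatocyte markers higher and 3 lower. Of 33 genes of the endocrine pancreas and glucose control, 5 rose and 3 fell (5 and 3 adjusted over the list alone). The median was 0.30 (camera adjusted p = 0.154). Called genes included igfbp1b (1.65) and igfbp1a (0.82), with falls named after their values were seen in pax6b (−0.93), PKLR (−0.88) and slc2a2 (−0.73), and equal totals gave 3 higher and 3 lower. Of 31 glucocorticoid responsive genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.24, camera adjusted p = 0.00185, adjusted p = 0.413 with an estimated correlation), with the collagenase gene mmp13a (2.62) and the glutamine synthetase gene glula (1.56) among the rises and, named after their values were seen, dusp1 (−0.98) and tdo2a (−0.46) as the falls. With equal totals 4 rose and 2 fell.

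Of 58 rod and cone phototransduction genes, 25 fell and 3 rose at 100 nM (30 and 3 adjusted over the list alone). Their median was −0.58 (camera adjusted p = 2.21e-08, adjusted p = 0.552 with an estimated correlation, fry adjusted p = 0.0567). The green cone opsin gene opn1mw1 went from 12150 ± 3700 to 2992 ± 704 normalised counts (SD, n = 3, log2 fold change −2.0 ± 0.24 SE, adjusted p = 3.38e-04) and the opsin kinase gene grk1b from 951 ± 346 to 138 ± 60. Beside opn1lw1, the rises were opn1mw2 (1.55) and gngt2a (1.11), both named after their values were seen. Of 46 lens crystallin and related genes, 1, crybb1l3 (−1.14, named after its value was seen), fell (0 and 1 adjusted over the list alone). The median was 0.04, or −0.14 with equal totals (camera adjusted p = 0.723). The circadian clock list had 15 of 38 genes higher and 1, hlfa (−0.57, named after its value was seen), lower (18 and 2 adjusted over the list alone). Their median was 0.29 (camera adjusted p = 6.98e-05, adjusted p = 0.266 with an estimated correlation). aanat2, which encodes the pineal enzyme of melatonin synthesis, went from 49 ± 6.93 to 293 ± 102, and nr1d4b (1.98) and nfil3 (1.43) rose too. With equal totals 8 clock genes rose and 4 fell.

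Of 52 cell cycle and DNA replication genes, 46 fell and 0 rose at 100 nM (48 and 0 adjusted over the list alone). The median was −0.87 (camera adjusted p = 2.53e-32, adjusted p = 0.131 with an estimated correlation). The spindle gene tpx2 went from 859 ± 51.4 to 330 ± 31.8 normalised counts (SD, n = 3, log2 fold change −1.38 ± 0.10 SE, adjusted p = 1.74e-05), the ribonucleotide reductase gene rrm1 from 2739 ± 128 to 1181 ± 103 (−1.22 ± 0.09 SE, adjusted p = 2.29e-05), and the mitotic kinase gene plk1 from 806 ± 15.7 to 389 ± 11.7 (−1.05 ± 0.08 SE, adjusted p = 2.44e-05). Of 37 cartilage and bone genes, 6 fell and 0 rose (6 and 0 adjusted over the list alone). Their median was −0.17 (camera adjusted p = 0.0895). Called genes included entpd5a (−1.33), hapln1b (−0.95) and hapln1a (−0.81), and 10 fell with equal totals.

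Of 55 muscle contraction genes, 9 rose and 3 fell (11 and 3 adjusted over the list alone, median 0.27, camera adjusted p = 0.0174, adjusted p = 0.562 with an estimated correlation, fry adjusted p = 0.0731), with the glycogen phosphorylase gene pygma from 5662 ± 1341 to 12566 ± 1545 normalised counts (SD, n = 3) and eno3 from 24211 ± 3118 to 47092 ± 6683. This call ended without control replicate 1 (0.135) or 100 nM replicate 1 (0.0695), and equal totals gave 6 higher and 5 lower. Of 75 oxidative phosphorylation genes, 6 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.18, or −0.01 with equal totals). Called genes included the muscle forms cox6a2 (1.19) and cox7a1 (0.75). The list was called higher (camera adjusted p = 0.00185, adjusted p = 0.653 with an estimated correlation, fry adjusted p = 0.257), but not without control replicate 2 (0.0678) or 100 nM replicate 1 (0.214), nor with equal totals (0.0864, 2 higher and 2 lower). Of 29 epidermis and keratin genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.154), with krt18 (0.86) among the rises. Of 31 ionocyte and calcium transport genes, 5 rose and 1, the ammonium transporter gene rhcga (−2.21), fell (5 and 1 adjusted over the list alone, median 0.18, or −0.00 with equal totals, camera adjusted p = 0.154), with the sodium pump gene atp1a1a.3 (1.07) among the rises. Of 41 neuron and glia markers, 3 rose and 4 fell (3 and 5 adjusted over the list alone, median −0.24, camera adjusted p = 0.363), with the myelin gene plp1b (1.48) and glula (1.56) higher and, named after their values were seen, syn1 (−1.71), gad2 (−1.47) and slc6a1b (−1.02) lower.

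The comparison of 30 nM with the control asked which changes were present at an intermediate concentration. opn1lw1 reached 1292 ± 43.7 normalised counts at 30 nM (SD, n = 3, log2 fold change 3.98 ± 0.24 SE, limma adjusted p = 3.14e-05) and sult3st4 rose from 52.7 ± 8.08 to 523 ± 55.9 (3.29 ± 0.19 SE, adjusted p = 3.14e-05). soat2 rose to 738 ± 180 (2.76 ± 0.27 SE, adjusted p = 0.00117) and scd to 155 ± 44.6 (2.97 ± 0.21 SE, adjusted p = 9.42e-05), with cyp2x12 (4.08), PTGR1 (2.80) and RETSAT (2.76), a name carried by more than 1 gene, also higher. The falls were led by immediate early genes, which cells switch on within minutes of stimulation: fosab went from 6044 ± 2594 to 648 ± 269 (−3.20 ± 0.43 SE, adjusted p = 0.00827), btg2 fell by 2.26, egr1 by 2.05 and dusp1 fell by 1.83 on the log2 scale. fosab lost its call without control replicate 3 (0.0516) or 30 nM replicate 2 (0.0542).

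At 30 nM, 2169 genes had an unadjusted p under 0.05, where chance alone would give 1120 on average, and the excess was not tested. The adjusted threshold was passed by 119 genes, 85 higher and 34 lower, 49 and 24 of them by more than 2-fold. The count was 75 without control replicate 1, 267 without control replicate 2 and 38 without control replicate 3; it was 52, 34 and 28 without 30 nM replicates 1, 2 and 3, and 179 without 100 nM replicate 2. With only the 2 groups in the fit it was 15 (15 higher, 0 lower), so that all 34 falls lost their calls there. With equal totals it was 62, of which 31 were higher and 31 lower. With the replicate number as a block it was 778 (416 higher, 362 lower). None of the RXR genes, pparg, cyp26a1 or cyp19a1b was called, with rxraa at −0.09 (adjusted p = 0.76) and pparg at −0.01 (adjusted p = 0.992).

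Of the 37 lists, camera called 23 at 30 nM, 19 higher and 4 lower, fry 3 and camera with an estimated correlation 0, its lowest adjusted p being 0.152. The 3 called by fry were LXR targets, heat shock, and retinoid and vitamin D signalling. Of 30 retinoid and vitamin D genes, 0 were called over all genes and 4 were higher adjusted over the list alone. Their median was 0.14, or 0.07 with equal totals (camera adjusted p = 0.00743, adjusted p = 0.152 with an estimated correlation, fry adjusted p = 0.038). LXR targets and fatty acid synthesis had 5 of 27 genes higher and 0 lower (10 and 0 adjusted over the list alone). The median was 0.28 (camera adjusted p = 5.87e-09, adjusted p = 0.152 with an estimated correlation, fry adjusted p = 0.00668). They were scd, abca1a (0.80, adjusted p = 0.0148), mylipa (0.76) and, named after their values were seen, fads2 (1.84) and fasn (0.54). abca1a lost its call without control replicate 3 (0.0827), without 30 nM replicate 1 (0.0663), 2 (0.0808) or 3 (0.0755), and with equal totals (0.0594). mylipa lost its call without control replicate 3 (0.133), 3 nM replicate 3 (0.0571), or 30 nM replicate 1 (0.133), 2 (0.0808) or 3 (0.117). fads2 and fasn lost theirs without 9 of the 12 libraries taken in turn (up to 0.161 and 0.151) and with equal totals (0.121 and 0.385), where 2 of the 27 genes rose. Lipoprotein and lipid absorption genes had 4 of 36 higher and 0 lower (9 and 2 adjusted over the list alone). Their median was 0.17 (camera adjusted p = 0.00875, adjusted p = 0.655 with an estimated correlation). Called genes included soat2, lcat (1.22, adjusted p = 0.00693, or 0.0506 with equal totals) and, named after its value was seen, abcg8 (1.94); the list's call ended without control replicate 1 (0.187) or 30 nM replicate 3 (0.0961), and with camera on ranks (0.184). abcg8 lost its call without 9 of the 12 libraries (up to 0.186) and with equal totals (0.121), where 1 of the 36 genes rose. Hepatocyte markers had 3 of 34 higher and 1 lower (5 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 2.67e-05, adjusted p = 0.467 with an estimated correlation), with fabp10a at 1.47 (adjusted p = 0.00827). fabp10a lost its call without 30 nM replicate 2 (0.0542) or 3 (0.0575) and with equal totals (0.0543), where 0 hepatocyte markers were higher and 1 was lower.

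In the heat shock and unfolded protein response list, 0 of 39 genes passed over all genes at 30 nM and 5 were lower adjusted over the list alone (median −0.22, camera adjusted p = 1.14e-06, adjusted p = 0.152 with an estimated correlation, fry adjusted p = 0.038), against a median of 0.32 at 100 nM. Cholesterol biosynthesis genes had a median of 0.30 at 30 nM, with 0 of 27 called (0 adjusted over the list alone, camera adjusted p = 3.88e-06, adjusted p = 0.324 with an estimated correlation), against −0.51 at 100 nM. Inflammation and acute phase genes were not called as a list at 30 nM (median −0.06, camera adjusted p = 0.097), with 2 of 39 higher, crp2 (1.97, adjusted p = 0.00211) and crp3 (1.72, adjusted p = 4.8e-04), and 5 lower (3 and 7 adjusted over the list alone). The exocrine pancreas list was lower, with 0 of 29 genes called (0 adjusted over the list alone, median −0.69, camera adjusted p = 8.39e-06, adjusted p = 0.48 with an estimated correlation). The oxidative phosphorylation list was higher with 0 of 75 genes called (median 0.18, camera adjusted p = 1.31e-08, adjusted p = 0.481 with an estimated correlation).

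The comparison of 3 nM with the control asked whether the lowest concentration changed any transcript. The genes that passed the threshold were mostly immediate early genes and lower: egr2a went from 290 ± 139 to 44.7 ± 10 normalised counts (SD, n = 3, log2 fold change −2.59 ± 0.32 SE, limma adjusted p = 0.0277), egr1 from 11084 ± 3450 to 2486 ± 865 (−2.17 ± 0.27 SE, adjusted p = 0.0277), and fosl1a, egr3 and cyr61 fell by 2.49, 1.81 and 1.26 on the log2 scale (adjusted p = 0.0277 each). In all 9 genes passed, 1 higher and 8 lower, among them sik1 (−1.44), named after its value was seen. egr2a, egr1, fosl1a, egr3 and cyr61 each lost the call without 8 to 10 of the 12 libraries taken in turn (adjusted p up to 0.244), and sik1 without 10 (up to 0.391) and with upper-quartile scaling (0.0769). The genes that led the list at higher concentrations did not pass at 3 nM: opn1lw1 had a log2 fold change of 1.27 (adjusted p = 0.196), soat2 of 0.68 (0.433), scd of 0.60 (0.407) and abca1a of 0.24 (0.484). An unadjusted p under 0.05 was reached by 2385 genes, against 1120 by chance on average, and the excess was not tested. The count was 0 with only the 2 groups in the fit, without the variance trend, and without any one of control replicate 3, 3 nM replicates 1 and 2, 30 nM replicates 1 and 2, and 100 nM replicates 1 and 3. It was 2 without control replicate 1, 4 without 3 nM replicate 3 or 30 nM replicate 3, 8 without 100 nM replicate 2 and 33 without control replicate 2. With the replicate number as a block it was 1234 (427 higher, 807 lower). Of the genes named at 100 nM and not called at 3 nM, 13 were called at 3 nM with that block. The 3 nM count thus depends strongly on a pairing that the labels do not give.

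At 3 nM camera called 9 of the 37 lists, 5 higher and 4 lower, while fry and camera with an estimated correlation called 0, the lowest adjusted p of the latter being 0.526, and 14 lists had an unadjusted camera p under 0.05. Of the 55 muscle contraction genes 0 were called over all genes and 6 were higher adjusted over the list alone (median 0.36, camera adjusted p = 6.19e-11, adjusted p = 0.526 with an estimated correlation). The oxidative phosphorylation genes had a median of 0.23 (camera adjusted p = 2.91e-13, adjusted p = 0.763 with an estimated correlation), and the lens genes one of 0.41 (camera adjusted p = 6.94e-08, adjusted p = 0.763 with an estimated correlation). Inflammation and acute phase genes were lower, with fosl1a the 1 called of 39 (1 higher and 7 lower adjusted over the list alone, median −0.17, camera adjusted p = 0.00153, adjusted p = 0.526 with an estimated correlation), a call that ended without control replicate 1 (0.0581). The number of lists called was 18 without control replicate 2.

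The comparison of 100 nM with 30 nM asked whether the upper concentrations differed from each other, with the control libraries entering the variance of the fit but not the difference. lyve1a rose from 79 ± 2.65 to 640 ± 3.51 normalised counts between them (SD, n = 3, log2 fold change 3.00 ± 0.14 SE, limma adjusted p = 3.47e-06), mmp13a from 126 ± 28.7 to 1480 ± 647 (3.47 ± 0.33 SE, adjusted p = 1.95e-04) and the small GTPase gene arf4b from 42 ± 4 to 459 ± 82.8 (3.41 ± 0.36 SE, adjusted p = 2.84e-04). hbz (4.17) and fosl1a (3.17) were higher as well, and fut9d (−3.11) and vwa10.1 (−2.61) lower. URGCP (−2.62, adjusted p = 0.0178) lost its call without 30 nM replicate 1 (0.0548), 2 (0.0617) or 3 (0.0618), rhcgl1 (−2.39, adjusted p = 0.0137) without 100 nM replicate 3 (0.0529) or 30 nM replicate 1 (0.0578), and mslna (−2.36, adjusted p = 0.0142) without 100 nM replicate 3 (0.0508) or 30 nM replicate 1 (0.0567). In all 2069 genes differed, 1185 higher and 884 lower at 100 nM, or 35.6% higher against 57.3% with equal totals (643 higher, 1164 lower). The count was 1124, 1170 and 1041 without 30 nM replicates 1, 2 and 3, 1316 without 100 nM replicate 1, and 1179 with only the 2 groups in the fit. With the replicate number as a block it was 4540 (2469 higher, 2071 lower).

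The 37 lists were tested between 100 and 30 nM as a comparison added after the data were seen, and camera called 17, 8 higher and 9 lower. With an estimated correlation 3 calls held: cell cycle and DNA replication, with 45 of 52 genes lower (48 adjusted over the list alone, median −0.85, adjusted p = 0.0426 with an estimated correlation), inflammation and acute phase, with 16 of 39 higher and 1 lower (23 and 1 adjusted over the list alone, median 0.81, adjusted p = 0.0286 with an estimated correlation), and heat shock and unfolded protein response, with 19 of 39 higher and 2 lower (21 and 4 adjusted over the list alone, median 0.48, adjusted p = 0.0426 with an estimated correlation). In cholesterol biosynthesis 17 of 27 genes were lower and 1 higher at 100 nM than at 30 nM (19 and 2 adjusted over the list alone). The median was −0.77 (camera adjusted p = 2.54e-11, adjusted p = 0.138 with an estimated correlation). Called genes included, named after their values were seen, sqlea (−2.28), lss (−2.10) and mvda (−1.42). In fatty acid oxidation 7 of 32 were lower and 0 higher (11 and 0 adjusted over the list alone). Their median was −0.22 (camera adjusted p = 8.77e-06, adjusted p = 0.157 with an estimated correlation). In the circadian clock list 13 of 38 were higher and 0 lower (16 and 0 adjusted over the list alone). Their median was 0.34 (camera adjusted p = 1.99e-08, adjusted p = 0.0808 with an estimated correlation). With equal totals 6 clock genes and 12 inflammation genes were higher, and 10 fatty acid oxidation genes lower.

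**Figure D2:**
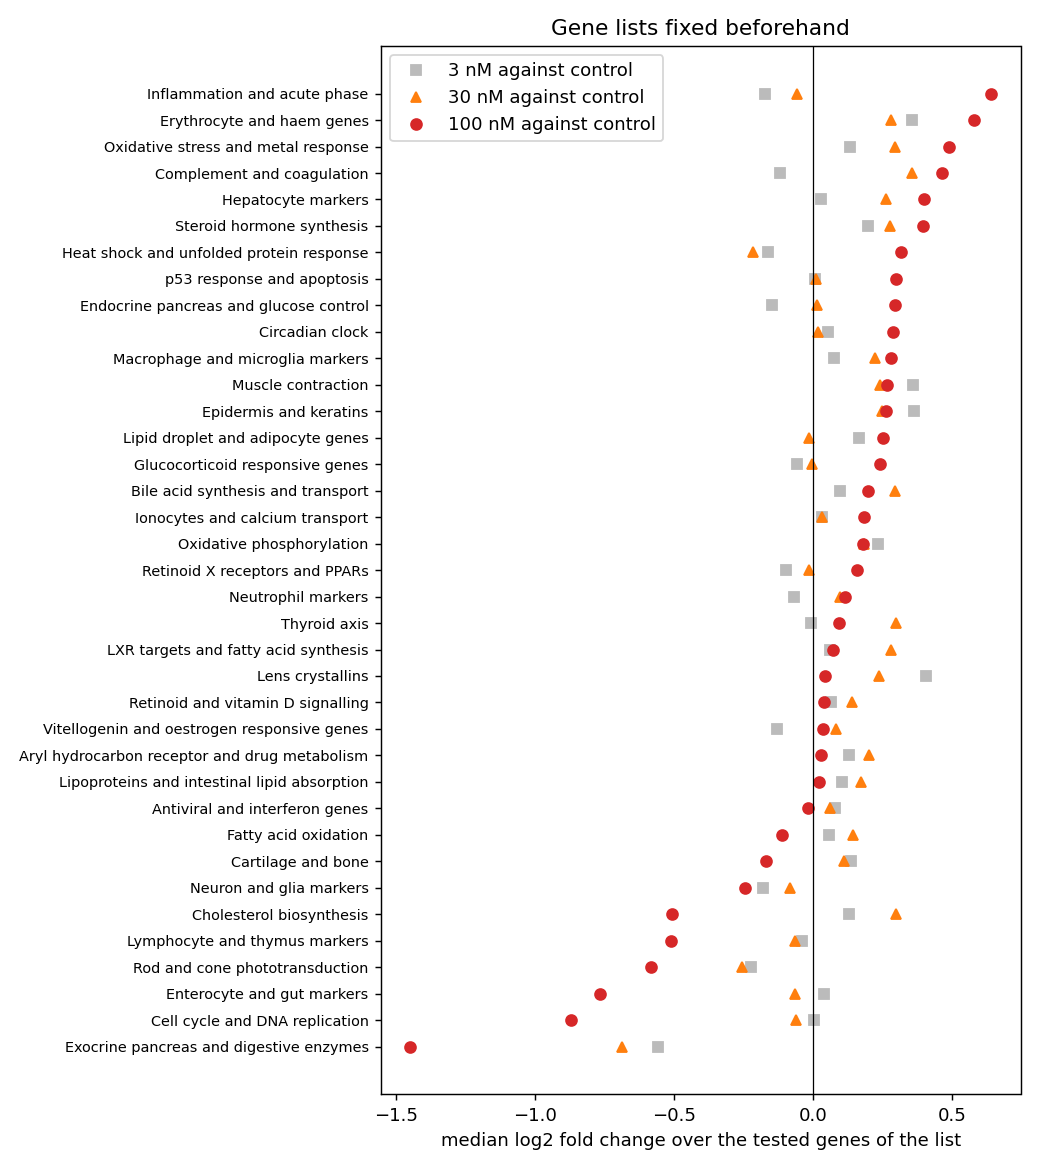
Median log2 fold change against control over the tested genes of each of the 37 gene lists (x axis, log2 units; 1 line of points per list on the y axis), with 1 point each for 3, 30 and 100 nM TBT. The cell cycle list had a median of −0.87 at 100 nM against −0.06 at 30 nM, and the cholesterol biosynthesis list −0.51 against 0.30. Medians of lists near 0 at 100 nM, such as LXR targets (0.07), turned negative with equal totals.

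Of the 119 genes changed at 30 nM, 102 had also changed in the same direction at 100 nM, 76 higher and 26 lower, and 2 in the opposite direction. Independent lists would share 8.18 higher and 2.68 lower genes, and unchanged groups simulated against the same controls shared a median of 0 and at most 0 in 50 draws, which leaves out the effects and does not measure how far shared controls raised the overlap. Both comparisons used the same 3 control libraries, which were too few to split, so part of the excess may come from the shared controls. The log2 fold changes had a covariance of 0.125 across genes, against 0.0408 on average in the simulation (−0.0441 to 0.283), and an r of 0.594 across genes, which are not independent replicates, against 0.426 on average and up to 0.941. The number of shared genes was 230 without control replicate 2, 34 without control replicate 3, 48, 32 and 28 without 30 nM replicates 1, 2 and 3, and 53 with equal totals. Between 30 and 100 nM, 21 of the 119 genes moved further from the control, 16 moved back toward it and 82 showed no called difference.

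The series title names a functional benchmark dose analysis, which asks at what concentration groups of genes depart from the control. Among the 4 groups, 2881 genes differed by the joint test (limma), 1803 without 100 nM replicate 1 and 1832 without 100 nM replicate 3. For 2754 of these the benchmark dose, the concentration at which the fitted curve had moved by 1 residual SD, lay between 0.3 and 100 nM, with a median of 27 nM, quartiles of 19.2 and 39.2 nM and a 5th percentile of 1.99 nM. It was under 3 nM for 182 genes, between 10 and 30 nM for 1343 and between 30 and 100 nM for 1111. The lowest list medians were those of macrophage markers (2.62 nM, 4 genes), hepatocyte markers (3.1 nM, 7 genes), lipoproteins and lipid absorption (3.66 nM, 10 genes), bile acid genes (5.30 nM, 9 genes), the thyroid axis (5.88 nM, 5 genes) and LXR targets (5.98 nM, 13 genes). Phototransduction genes had a median of 21.7 nM (23 genes), inflammation genes 26.9 nM (20), cell cycle genes 28.9 nM (45), heat shock genes 60.8 nM (22) and cholesterol biosynthesis genes 64.2 nM (13). These list medians have no test. Each fitted curve can only rise or only fall with concentration. The heat shock list, however, had a median log2 fold change of −0.22 at 30 nM and 0.32 at 100 nM. That of the cholesterol list was 0.30 and −0.51. An opposite shift at 30 nM enters the residual SD of such a curve, so these high doses do not show that the lists were unmoved below them. Doses under 3 nM lie between the control and the lowest concentration tested and rest on the fitted curve. At 3 nM 0 of 23 macrophage, 0 of 34 hepatocyte and 0 of 36 lipoprotein genes were called. The same held for 0 of 25 bile acid, 0 of 19 thyroid and 0 of 27 LXR genes. Camera called none of these lists at 3 nM (adjusted p from 0.193 to 0.83), so the low medians do not show a departure there.

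The median benchmark dose was between 22.4 and 26.7 nM with any one library left out and the genes chosen anew. With the genes held fixed it was between 25.8 and 27.7 nM. It was 51.6 nM at 2 SD and 2.72 nM by linear interpolation between group means.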

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

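Equal totals, the robust prior, the fit without a variance trend, the lists tested between 100 and 30 nM, and upper-quartile scaling of list counts, benchmark doses and the overlap were chosen only after the data were seen, and the other alternatives before. Count tools (edgeR, DESeq2, voom, relative log expression and TMM factors, unrounded counts) were not run, because the values are not counts. Outside the changes given here, gene and list counts stayed within 1.5 times of their reported values under the scalings, filters, pseudocount, robust prior and ranks. Libraries with the same replicate number tended to deviate together: 13 of 18 such pairs had deviations correlated above 0.1 (−0.0202 to 0.578, median 0.371, against −0.0862 for other pairs), and 10 of 12 libraries correlated best with their own number. This is a hint of a shared batch. All pairs numbered 1 or 2 correlated at 0.293 to 0.578. On the first principal component every group ran from number 1 over 3 to 2. Of the pairs numbered 3, 5 lay under 0.1. Deviations sum to 0 within a group of 3, so opposite shifts of numbers 1 and 2 leave little for number 3. Its low values therefore do not count against a batch. The labels do not name one, so the numbers were not used to pair the libraries. With the number as a replicate block, 1234, 778 and 7678 genes were called at 3, 30 and 100 nM, 4540 between 100 and 30 nM and 7570 among the 4 groups, and the overlap of 30 and 100 nM was 635; the cause was not tested. The block ended the list calls of RXRs and PPARs at 100 nM (0.0534), cell cycle at 30 nM (0.0659) and lens genes between 100 and 30 nM (0.0534). List calls not described singly in the results also ended: cell cycle at 30 nM with upper-quartile scaling (0.0807) or the stricter filter (0.0534), macrophage markers at 30 nM with that filter (0.0836), and with equal totals cartilage and bone at 30 nM (0.0601), exocrine pancreas (0.0721) and phototransduction (0.0684) at 3 nM, and RXRs and PPARs (0.121) and lens genes (0.118) between 100 and 30 nM. Lens genes also lost theirs with upper-quartile scaling (0.0592).

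With only the 2 groups compared, the counts were 0, 15, 1172 and 1179 at 3, 30, 100 and 100 against 30 nM, in fits with fewer libraries; 23 of the named calls at 100 nM, 22 at 30 nM and 5 at 3 nM were lost. Without a variance trend the 3 nM count was 0. Equal totals gave 62 genes at 30 nM, an overlap of 53 and a median benchmark dose of 25.4 nM. With a 1.5-fold minimum 2587 genes remained at 100 nM. With an estimated correlation the list calls numbered 0 at 3, 30 and 100 nM and 3 between 100 and 30 nM, and with fry 0, 3 and 13 against the control. The benchmark dose median was 51.6 nM at 2 SD, 2.72 nM by interpolation and 25.5 nM over 1.5-fold genes. Interpolation gives at most 3 nM to a gene whose 3 nM mean lies 1 SD or more from the control. That held for 54.6% of the 2881 genes, which puts its median under 3 nM. How many of these shifts were noise cannot be told, since the genes were selected by a joint test that includes 3 nM. The cause of the other differences was not tested.

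Leaving out 1 library gave 0 to 33 genes at 3 nM, 28 to 267 at 30 nM, 2289 to 4621 at 100 nM, 1041 to 2492 between 100 and 30 nM and 1803 to 3344 among the 4 groups; 8 to 18, 18 to 25, 17 to 21 and 17 to 21 lists at 3, 30, 100 and 100 against 30 nM; a median benchmark dose of 22.4 to 26.7 nM; and an overlap of 28 to 230. Without control replicate 2 the 3 nM, 30 nM and overlap counts were highest, at 33, 267 and 230. Reversed directions were those of epidermis and keratin genes at 30 nM without control replicate 2 (adjusted p = 0.936, from 2.65e-05 up) and lens genes between 100 and 30 nM without 30 nM replicate 2 (adjusted p = 0.96, from 2.15e-04 up); the cause was not tested. Raw totals were at least 23800000 in the 11 resolved libraries, and 22404 of 26816 genes had values high enough to be tested; how depth limited the calls was not tested.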

Other observations

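The lists of this part other than the gut, pancreas, hepatocyte and cell cycle lists were written after the data were seen, so their p-values are descriptive, and the tests of control handling, of any 1 library and all digestive organs for the gut and pancreas genes, of the scaling of cell cycle genes, and of the splits for lists between 100 and 30 nM were chosen only after the result was seen. Genes of the integrated stress response, by which cells facing amino acid shortage or misfolded proteins reprogram translation, rose in 18 of 28 cases at 100 nM and fell in 0 (19 and 0 adjusted over the list alone, median log2 fold change 0.75, camera adjusted p = 2.28e-11, adjusted p = 0.0122 with an estimated correlation). ppp1r15b went from 158 ± 20.7 to 748 ± 222 normalised counts (SD, n = 3, log2 fold change 2.2 ± 0.20 SE, limma adjusted p = 7.14e-05), atf5b from 815 ± 11 to 2428 ± 269, and the serine synthesis gene phgdh rose by 0.93. This list shares trib3, ddit3, sesn2, asns and atf4 genes with the heat shock list. Aminoacyl tRNA synthetase genes rose in 12 of 19 cases and fell in 0 (14 and 0 adjusted over the list alone, median 0.55, camera adjusted p = 8.78e-10, adjusted p = 0.0671 with an estimated correlation), among them nars (0.73) and eprs (0.83). Carriers of amino acids and monocarboxylates rose in 13 of 23 cases and fell in 0 (15 and 1 adjusted over the list alone, median 0.62, adjusted p = 0.0255 with an estimated correlation), with slc16a9a going from 554 ± 210 to 3753 ± 441.

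Autophagy and lysosome genes rose in 19 of 36 cases at 100 nM and fell in 0 (22 and 1 adjusted over the list alone, median 0.43, camera adjusted p = 9.98e-09, adjusted p = 0.0122 with an estimated correlation). The autophagy receptor gene sqstm1 went from 3765 ± 1351 to 11936 ± 3229 normalised counts (SD, n = 3), the lysosomal regulator gene tfe3a rose by 1.35 and the cathepsin genes ctsd and ctsla by 0.95 and 0.94 on the log2 scale. Proteasome genes rose in 9 of 34 cases and fell in 0 (11 and 0 adjusted over the list alone, median 0.24, adjusted p = 0.338 with an estimated correlation). Of 76 cytosolic ribosomal protein genes 0 were called at any concentration, with medians of 0.35, 0.24 and 0.35 at 3, 30 and 100 nM (adjusted p = 0.69, 0.387 and 0.441 with an estimated correlation).

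Immediate early genes had a median log2 fold change below 0 at every concentration. Of 35 such genes, 0 rose and 6 fell at 3 nM, 0 and 16 at 30 nM and 2 and 17 at 100 nM, with medians of −1.20, −1.34 and −0.59. For 14 of the 35 all 9 treated libraries lay below all controls, and no test of the list as a whole is given, since it was written after such falls were seen. The tables argue against 1 control library as the cause (highest median at 3 nM without a control library −0.92) and against the scaling (highest median under other scalings −1.16). Control larvae handled or collected apart from the treated larvae remain a candidate explanation that cannot be told apart from a response complete at 3 nM, since the median difference of 30 nM from 3 nM was −0.15 and the labels give no handling order. At 100 nM, 9 of the 35 genes were higher than at 30 nM and 0 lower, with a median of 0.31. Either explanation alone would put all concentrations at the same level, so neither gives this partial return, whose cause was not tested.

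Gut and exocrine pancreas genes were lower at 100 nM, with a median of −0.95 over 67 genes. Neither list was called with an estimated correlation (adjusted p = 0.562 and 0.436), and the libraries overlapped: the mean log2 value of these genes was 10.44 in 100 nM replicate 2 and 10.19 in control replicate 1. The controls spread from there to 11.21 in control replicate 2. Within each replicate number the 100 nM library lay below the control, though the labels do not pair them. The values were 8.92 and 10.19 for number 1, 10.44 and 11.21 for number 2, and 9.6 and 10.89 for number 3. The median without control replicate 2 was −0.72, and the highest with any 1 library left out was −0.57, which argues against a single library as the sole cause. The hepatocyte markers did not fall alike, and their median of 0.40 stayed at least 1.12 above that of gut and pancreas with any library left out. Reading this as organ share takes hepatocyte transcripts as a measure of liver share alone, which was not tested. A lower share of all digestive organs therefore stays undecided. An effect of TBT on these organs stays open as a hypothesis, and no mechanism was tested.

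Cell cycle genes were lower at 100 nM, with a median of −0.87 over 52 genes (adjusted p = 0.131 with an estimated correlation). Neither the scaling (highest median under other scalings −0.87) nor 1 library (highest median without a library −0.79) accounts for it. An effect of TBT stays open as a hypothesis, and no mechanism was tested.

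Other splits of the libraries were counted. For comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. The gene counts of the real split and the highest other split were 9 and 0 at 3 nM, 119 and 0 at 30 nM, 3926 and 3734 at 100 nM and 2069 and 1 between 100 and 30 nM, with 1 of 10 splits as large in each. The list counts were 9 and 19 at 3 nM (9 of 10 splits as large), 23 and 21 at 30 nM (1 of 10), 20 and 20 at 100 nM (2 of 10) and 17 and 23 between 100 and 30 nM (5 of 10). The split with 3734 genes set 100 nM replicates 1 and 3 with control replicate 1 against the rest. These libraries lay at −56.6, −30.4 and −28.8 on the first principal component, and the rest at 23.9 or higher. The split thus points to a structure of the samples that ran with the replicate numbers rather than the groups. For the 2881 genes that differed among the 4 groups, 1 of 100 splits was as large, which was the real one, and the highest other gave 1732. For the overlap of 102 genes, 2 of 100 splits were as large, the real one among them, and the other gave 1443. The drawn splits ignored the replicate numbers, and counts of 1732 and 1443 point to a structure of the samples other than their groups. Neither share therefore excludes chance. The share for the overlap also does not measure how far the shared controls raised it.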
